A study of Gallus gallus with 27 samples.

How the data were processed

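ATAC-seq, which reads open chromatin by inserting sequencing adapters into accessible DNA with a transposase, was applied to cells sorted from the vagal region of electroporated chick embryos. The labels list 27 samples in 9 groups of 3. At Hamburger-Hamilton stages 18 and 25 (HH18 and HH25) the groups are double-positive cells (NC2-positive and E2-positive), E2-only cells (NC2-negative and E2-positive) and double-negative cells. The labels name citrine for both reporters, so how their signals were told apart is not given in the sources used here, and what each group holds rests on the labels. NC2 and E2 are enhancer reporters, known from background to belong to the neural crest genes FOXD3 and SOX10. Per the labels' protocols, nuclei were tagmented for 20 min, libraries were amplified for 11 PCR cycles and sequenced as 40 bp paired-end reads, and biological replicates were taken at each stage.

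The deposited values are whole-number counts of reads for 18 used libraries over a common set of 140062 intervals, described per the labels as raw. Of these intervals 140061 are 200 bp wide and 1 is 394 bp wide. The submitters' processing notes name Bowtie 1.0.0, MACS2, HOMER 4.7 and the genome build galGal5, without their roles; how intervals were chosen, how duplicates and mitochondrial reads were treated, and whether read ends were shifted for the transposase are not given in the sources used here. Coordinates are given as the file lists them, and whether they count from 0 or 1 is not given in the sources used here. The lowest count in every used library was 1, so a deposited 1 may stand for 0 reads. In the shallowest library 22220 intervals held 2 and 9283 held 3, an excess of even values that would arise where both reads of a pair were counted. The ratio of intervals with 2 to those with 3 was 1.076 to 2.394 in HH18 and 0.771 to 0.987 in HH25 libraries; intervals with 4 exceeded the mean of those with 3 and 5 in all 18 libraries, by a factor of 1.04 to 1.8.

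Columns were matched to samples by name. A further 9 columns of per-sample values carry a stage that differs from the labels and were not used in any step, so the HH10 groups are not analysed here and the planned fit over 27 libraries was made over 18. No genome or annotation of the galGal5 build was used, so the planned gene assignment, gene list tests, motif tests and GC correction were not made, and intervals are named by position alone.

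Library totals ran from 992341 reads (HH18 negative replicate 2) to 6976050, with the next lowest at 2586375. A floor of 3 counts corresponds to 3 CPM in the shallowest library and 0.479 CPM in the deepest. Amplified reads are not independent molecules, so floors cover counting error only. Spearman correlations of libraries within a group were 0.69 to 0.91, and between groups 0.27 to 0.78. The chi-square per degree of freedom between replicates was 2.03 to 2.9 over intervals. Independent reads alone would give about 1 and pairs counted as 2 reads about 2, so sampling noise is not excluded for the lowest pairs. Each library was kept as 1 replicate, since the labels name biological replicates and no 2 libraries were identical.

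Counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr left 134020 intervals, libraries were scaled by TMM, and a quasi-likelihood model with 1 mean per group was fitted to the 18 libraries together. An interval was called at a Benjamini-Hochberg adjusted p below 0.05. CPM values use the TMM-scaled totals, log2 fold changes are those of the model, and their standard errors were derived from the F statistic. All adjusted p values of single intervals come from this edgeR test. The first-named group of each comparison is the numerator.

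The procedure was tested on simulated counts with 200 changed intervals per comparison, 100 at each fold size. An initial requirement that over 80% of 4-fold changes be recovered was not met and was dropped; no other limit on recovery took its place. For HH18 double-positive against double-negative cells 59% of 4-fold and 8% of 2-fold changes were recovered among 132785 tested intervals, and for HH25 E2-only against double-negative cells 72% and 16% among 132737. The 4-fold recovery for HH18 double-positive against double-negative cells was 39.6% below and 76.9% above the median abundance. All recovered changes had the right sign, and 5 of 72 calls in that comparison were false. With only 200 intervals changed, the adjustment was stricter than in the data, where 42871 intervals were called in that comparison. These recoveries are therefore not the power in the data, which was not measured. Recovery was lower below the median abundance, so absence of a call is taken as weak evidence at low counts.

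Named intervals followed a rule fixed before the data were examined: the 6 higher and 6 lower intervals with the largest absolute log2 fold change among those called, not overlapping in CPM between groups and above the median abundance, or 4 and 4 across stages and for the interaction, where non-overlap does not apply. Between 7855 and 37584 intervals per pairwise comparison met these criteria; 3 libraries against 3 do not overlap by chance in 10% of cases. Where all libraries of the lower group stood at 1, the report gives the ratio of counts summed over each group, per summed TMM-scaled total. Its 95% binomial interval takes each count as independent and is too narrow where both reads of a pair were counted. Where a 1 stands for 0 reads these counts set no such ratio. Other folds with few counts in the lower group rest nearly as much on that lowest value, which their standard errors do not cover.

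Alternatives were library totals alone, median-of-ratios factors, loess offsets with span 0.3, DESeq2 1.42.0, no filter, the compared groups alone, a log2 fold change of at least 1, thinning to the lowest total, a replicate block and leaving out each library. Figures were drawn with matplotlib 3.10.9.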

Results

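Chromatin accessibility was measured in double-positive, E2-only and double-negative cells of the chick vagal region at HH18 and HH25, with 3 libraries in each of 6 groups. The double-positive cells were sorted as positive for the signals of both neural crest enhancer reporters, the E2-only cells for 1 of them. Totals were 992341 to 6976050 reads at HH18 and 2609023 to 5559179 at HH25. The first principal component held 38.2% and the second 21.7% of the variance of log2 CPM with a pseudocount of 2.

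**Figure D1:**
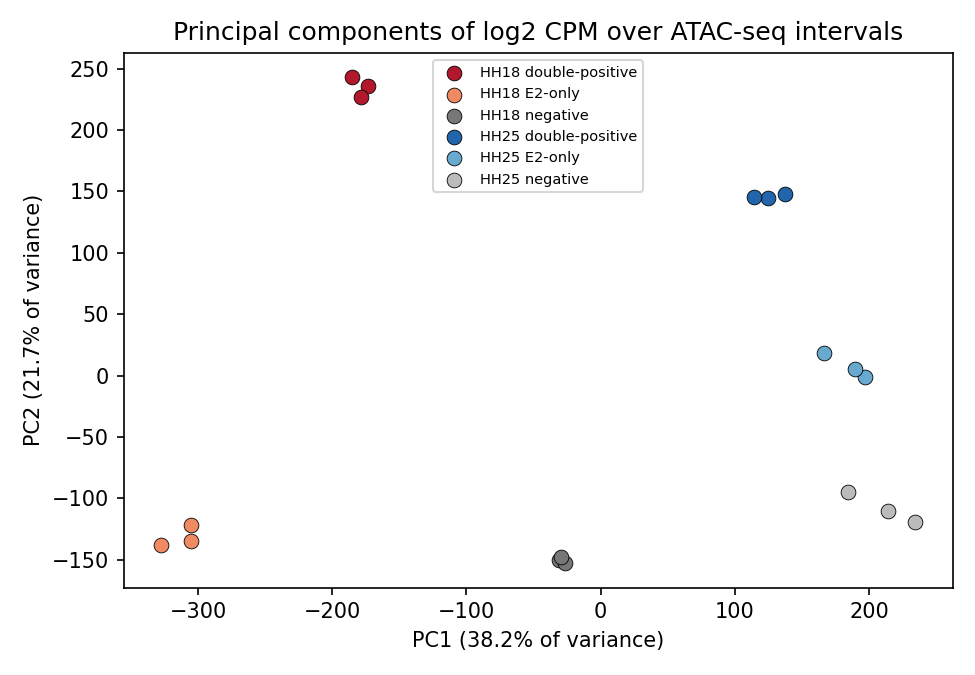
Principal components of log2 CPM over the 134020 tested intervals, 1 point per library coloured by group. PC1 (38.2% of variance) is on the x axis and PC2 (21.7%) on the y axis; the 3 libraries of each group lie together, and HH18 E2-only lies farthest to the left.

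The first comparison asked where HH18 cells sorted as positive for both reporters differed from cells negative for both. Double-positive cells were more accessible at 24510 and less accessible at 18361 of 134020 intervals, with median log2 changes of 2 and -1.58. The calls varied with chromosome class. Higher calls made up 21% of intervals on chromosomes 1 to 5, 12.5% on 11 to 33 and 7.2% on contigs outside the assembled chromosomes. Lower calls made up 11%, 19.2% and 24%. No GC correction was made, and the cause was not tested. An interval on chromosome 1 at 159715210 to 159715410 stood at 75 CPM ± 6.34 (SD, n = 3) in double-positive cells and 1.05 ± 0.857 in negative cells (log2 fold change 6.51, SE 0.39, adjusted p = 1.6e-27). Chromosome 8 from 15875489 to 15875689 was higher, at 34 CPM ± 3.52 against 0.537 ± 0.404 in negative libraries all at the lowest value (ratio of summed counts 86.7, 95% counting interval 29.4 to 423). In the other direction, chromosome 4 from 84176858 to 84177058 held 31.4 CPM ± 14.7 in negative and 0.355 ± 0.024 in double-positive cells (ratio of summed counts 92.6, interval 31.3 to 452). An interval on chromosome 2 at 118597215 to 118597415 fell from 36.4 CPM ± 13.4 in negative to 0.698 ± 0.313 in double-positive cells (log2 -5.61, SE 0.46, adjusted p = 1.3e-19). Scaling by library totals alone shifted the median log2 change of all intervals to -0.27 and the split to 20828 higher and 26585 lower, so which direction held more calls depended on the scaling. With all libraries thinned to the lowest total 55266 intervals were tested and 22291 called.

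HH18 E2-only cells, compared with negative cells to describe the NC2-negative and E2-positive population, were higher at 26650 intervals and lower at 19817. Median log2 changes were 1.62 and -1.74. Higher calls made up 21.7% of intervals on chromosomes 1 to 5, 16.8% on 11 to 33 and 8.6% on contigs outside the assembled chromosomes. Lower calls made up 13.3%, 16.5% and 24.7%, and the cause was not tested. Chromosome 1 from 153949737 to 153949937 was higher, at 679 CPM ± 127 in E2-only and 25.9 ± 5.5 in negative cells (log2 4.78, SE 0.17, adjusted p = 1.4e-44). It stood at 674 CPM ± 83.1 in double-positive cells. Chromosome Z from 18866381 to 18866581 stood at 34.3 CPM ± 6.04 in E2-only cells against 2.63 ± 0.439 in negative and 2.83 ± 0.19 in double-positive cells (log2 against negative 3.77, SE 0.34, adjusted p = 2.9e-16). Chromosome 3 from 8076075 to 8076275 was lower, at 0.419 CPM ± 0.253 against 30.2 ± 11.8 (log2 -6.21, SE 0.49, adjusted p = 1.5e-18). Its E2-only counts summed to 5 over the 3 libraries, near the lowest value. With library totals alone the split was 21158 higher and 27885 lower, and the median shifted to -0.23. After thinning 18541 intervals were called.

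Against HH18 E2-only cells, HH18 double-positive cells were higher at 23771 and lower at 24035 intervals, with median log2 changes of 1.95 and -1.56. On chromosome 14 the interval 6537281 to 6537481 was higher in double-positive cells, at 15.9 CPM ± 0.945 against 0.272 ± 0.144 (ratio of summed counts 69.5, 95% counting interval 23.3 to 341). On chromosome 1 the interval 126107674 to 126107874 stood at 37.8 CPM ± 5.57 in double-positive and 0.706 ± 0.24 in E2-only cells (log2 5.57, SE 0.38, adjusted p = 1.2e-24). Higher in E2-only cells was chromosome 5 from 17281200 to 17281400, at 40.8 CPM ± 2.14 against 1.26 ± 0.901 (log2 -4.94, SE 0.37, adjusted p = 7.9e-22). Chromosome 6 from 8058429 to 8058629 stood at 29.1 CPM ± 0.431 in E2-only and 0.829 ± 0.563 in double-positive cells (log2 -5.09, SE 0.42, adjusted p = 1.2e-19). After thinning to the lowest total 19392 intervals were called, 10176 higher and 9216 lower. With loess offsets the split was 22386 higher and 25723 lower, and with no filter 21597 and 28652. Which direction held more calls thus depended on the processing.

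At HH25 the same question was asked of double-positive against negative cells. Double-positive cells were higher at 19420 and lower at 13115 intervals, with median log2 changes of 1.73 and -1.29. Chromosome 4 from 74230266 to 74230466 stood at 15.4 CPM ± 4.78 in double-positive and 0.508 ± 0.136 in negative cells (log2 4.8, SE 0.46, adjusted p = 2e-15). Chromosome 11 from 17174473 to 17174673 was at 9.65 CPM ± 1.8 against 0.309 ± 0.162 (log2 4.74, SE 0.56, adjusted p = 9.1e-12). Its negative counts summed to 5 over the 3 libraries, near the lowest value. Lower in double-positive cells was chromosome 3 from 22208607 to 22208807, at 0.914 CPM ± 0.525 against 41.1 ± 13.1 (log2 -5.52, SE 0.47, adjusted p = 1.2e-13). Chromosome 1 from 182651084 to 182651284 was lower as well, at 1.18 CPM ± 0.76 against 42.1 ± 14.8 (log2 -5, SE 0.43, adjusted p = 9.6e-14). Thinned to the lowest total, the libraries gave 11839 calls.

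HH25 E2-only cells differed from negative cells at fewer intervals, 7165 higher and 6889 lower, with median log2 changes of 1.34 and -1.33. Chromosome 1 from 115762750 to 115762950 was higher, at 9.82 CPM ± 1.94 against 1.19 ± 0.686 (log2 3.1, SE 0.41, adjusted p = 2.5e-09). Chromosome 4 from 74230266 to 74230466 was again among the highest, at 4.86 CPM ± 2.56 against 0.508 ± 0.136 (log2 3.14, SE 0.56, adjusted p = 1.1e-05). Both HH25 comparisons that name this interval use the same 3 negative libraries, in which its counts summed to 8, so they are not separate evidence. Lower in E2-only cells were chromosome 5 from 40117729 to 40117929, at 0.487 CPM ± 0.299 against 22.2 ± 7.12 (log2 -5.39, SE 0.44, adjusted p = 3.6e-18), and chromosome Z from 6515075 to 6515275, at 0.551 CPM ± 0.296 against 23.9 ± 8.06. With library totals alone the split was 9140 higher and 5488 lower. DESeq2 called 7921 intervals, and 8990 were called without HH25 negative replicate 2. After thinning to the lowest total 2597 were called, 1051 higher and 1546 lower, so which direction held more calls turned.

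Against HH25 E2-only cells, HH25 double-positive cells were higher at 11373 intervals and lower at 4250, with median log2 changes of 1.4 and -1.26. Chromosome 24 from 1705285 to 1705485 stood at 18.3 CPM ± 8.49 in double-positive and 2.14 ± 1.09 in E2-only cells (log2 2.99, SE 0.35, adjusted p = 4.6e-10). Chromosome Z from 21499755 to 21499955 was at 16.2 CPM ± 5.35 against 2.25 ± 0.365 (log2 2.87, SE 0.35, adjusted p = 7.6e-10). Lower in double-positive cells was chromosome 6 from 5455527 to 5455727, at 0.748 CPM ± 0.025 against 5.87 ± 1.4 (log2 -2.92, SE 0.57, adjusted p = 8.7e-05). The share of called intervals that were higher was 72.8% with TMM, 62.1% with loess offsets (9730 higher, 5940 lower), 62% with median-of-ratios factors (9643 and 5902) and 56.9% with library totals alone (9112 and 6900). DESeq2 called 9851 intervals and 4592 were called after thinning to the lowest total.

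**Figure D2:**
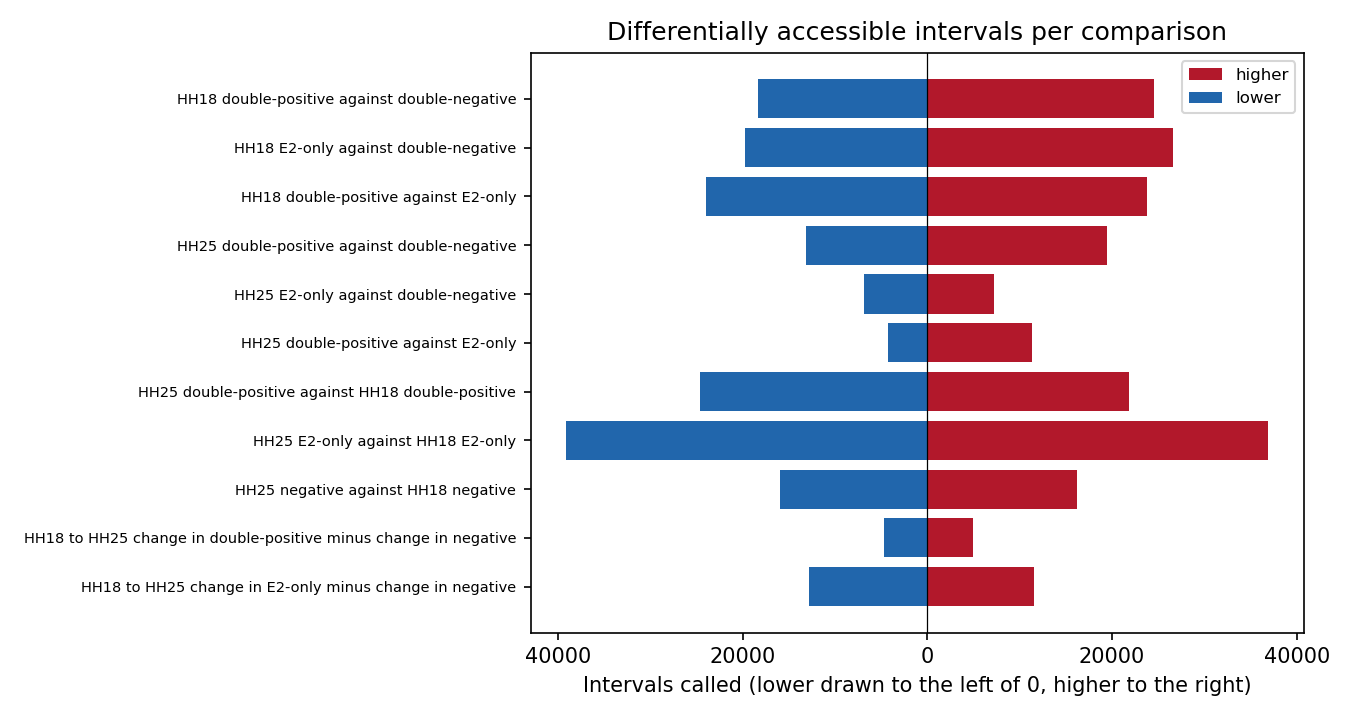
Intervals called in each comparison at an adjusted p below 0.05 (x axis, number of intervals; bars to the right are higher and bars to the left lower in the first-named group). The HH25 against HH18 comparison of E2-only cells has the longest bars, 36944 higher and 39174 lower.

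The stages were compared within each population, with the negative cells as background. Any difference in preparation or sequencing between the stages cannot be told apart from stage in these counts. The ratio of intervals with 2 to those with 3 differed by stage, at 1.076 to 2.394 in HH18 and 0.771 to 0.987 in HH25 libraries. Double-positive cells gained accessibility from HH18 to HH25 at 21883 intervals and lost it at 24670. Chromosome 15 from 8048768 to 8048968 rose from 0.355 CPM ± 0.024 to 17.6 ± 2.19 (ratio of summed counts 49.1, 95% counting interval 16.5 to 240). Chromosome Z from 63108857 to 63109057 fell from 47.4 CPM ± 7.82 to 0.622 ± 0.214 (log2 -6.14, SE 0.4, adjusted p = 2.7e-24). With library totals alone the split was 27866 higher and 19086 lower, and the median log2 change of all intervals was 0.14. After thinning 19560 intervals were called.

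E2-only cells changed at more intervals between the stages, 36944 higher and 39174 lower at HH25. Chromosome 3 from 84030966 to 84031166 rose from 0.272 CPM ± 0.144 to 26.6 ± 1.09 (ratio of summed counts 116, 95% counting interval 39.5 to 566). Chromosome 10 from 10168497 to 10168697 fell from 46.9 CPM ± 4.03 to 0.281 ± 0.119 (log2 -7.23, SE 0.4, adjusted p = 2.1e-31). Its HH25 counts summed to 4 over the 3 libraries, so the size of this fold rests on values near the lowest. Chromosome 4 from 80235297 to 80235497 fell from 52.3 CPM ± 9.19 to 0.551 ± 0.296 (log2 -6.48, SE 0.35, adjusted p = 1.4e-31). With library totals alone the split was 48049 higher and 30270 lower, with a median of 0.32. Thinning to the lowest total left 26252 calls.

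Negative cells gained accessibility at 16178 intervals and lost it at 15926. Chromosome 7 from 32089694 to 32089894 rose from 0.855 CPM ± 0.276 to 34.8 ± 1.38 (log2 5.41, SE 0.43, adjusted p = 5.4e-19). Chromosome 6 from 35247830 to 35248030 fell from 22.3 CPM ± 10.2 to 0.618 ± 0.334 (log2 -4.83, SE 0.44, adjusted p = 1.5e-15). Without HH18 negative replicate 1 the count of called intervals fell from 32104 to 19742, and after thinning to the lowest total it was 9350 (4426 higher, 4924 lower).

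The interaction tested whether the HH18 to HH25 change in double-positive cells differed from that in negative cells. It was higher at 4886 intervals and lower at 4658. Chromosome 7 from 2924250 to 2924450 was among the higher (adjusted p = 1.5e-06). Its double-positive mean went from 0.355 CPM ± 0.0237 at HH18, all 3 libraries at the lowest value, to 7.45 ± 2.11 at HH25, while its negative mean went from 8.08 ± 1.72 to 3.93 ± 1.48. Chromosome 3 from 69491735 to 69491935 was lower (adjusted p = 1.5e-06). There the double-positive mean went from 13.6 CPM ± 3.83 to 8.6 ± 0.92 and the negative mean from 0.537 ± 0.404, again with all 3 libraries at the lowest value, to 8.15 ± 0.539. No fold is given for these 2, since it would rest on that lowest value. With library totals alone the split was 7555 higher and 3207 lower, and the median was 0.17. The count was 6260 without HH18 double-positive replicate 1, 6346 without HH18 negative replicate 1, 5745 without HH18 negative replicate 3, and 2116 after thinning to the lowest total.

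Calls at the stages were then overlapped to ask how much of the accessibility pattern was shared. For double-positive against negative cells, 13284 intervals were higher at both stages where independent lists would share 3552, and 5292 were lower at both where independent lists would share 1797. The 5292 fell to 3508 without HH25 double-positive replicate 3 and to 3021 at an adjusted p below 0.01. Of the HH18 higher intervals 54.2% were called higher at HH25, and 187 were called lower there. A further 11039 were higher at HH18 and not called at HH25, and the interaction test was passed by 2667 of these. For E2-only against negative cells, 1659 intervals (691 at an adjusted p below 0.01) were higher at both stages against 1425 for independent lists, and 3237 were lower at both against 1019. Between double-positive and E2-only cells, 7871 were higher at both stages (2017 for independent lists) and 861 were lower at both (762). The 861 became 477 without HH25 double-positive replicate 3, 243 at an adjusted p below 0.01 and 1317 with loess offsets. Across intervals, which are not independent replicates, the Pearson correlation of log2 changes between stages was 0.61 for double-positive against negative, 0.26 for E2-only against negative and 0.33 for double-positive against E2-only. The stages share no libraries, but both were called from 1 fit, and simulated recovery rose with abundance. Calls can therefore coincide more often than in independent lists without a shared pattern. The excesses of 1659 over 1425 and of 861 over 762 are small. Of the HH18 higher calls of E2-only cells 223 were called lower at HH25, against the 1659 called higher. Of the HH18 lower calls in double-positive against E2-only cells 458 were called higher at HH25, against 861 lower. Such coincidence would not favour 1 direction, so these counts go against it as the whole cause. Yet of the HH25 calls in these 2 lists only 55.8% and 51.2% had the same sign at HH18. It was therefore not excluded for them.

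**Figure D3:**
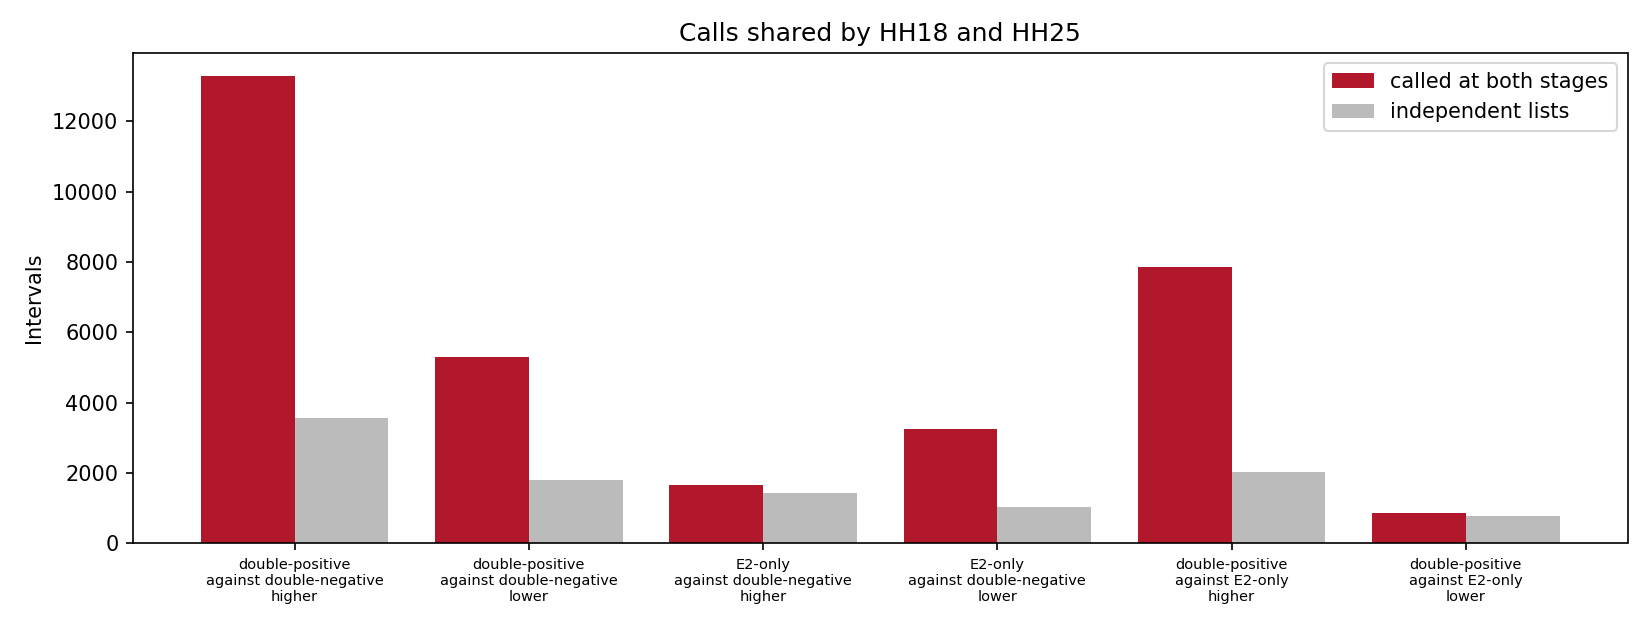
Intervals called in the same direction at HH18 and HH25 (y axis, number of intervals) for each comparison and direction, beside the number that independent lists of the same sizes would share. For double-positive against negative cells 13284 intervals were higher at both stages, against 3552 for independent lists.

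**Figure D4:**
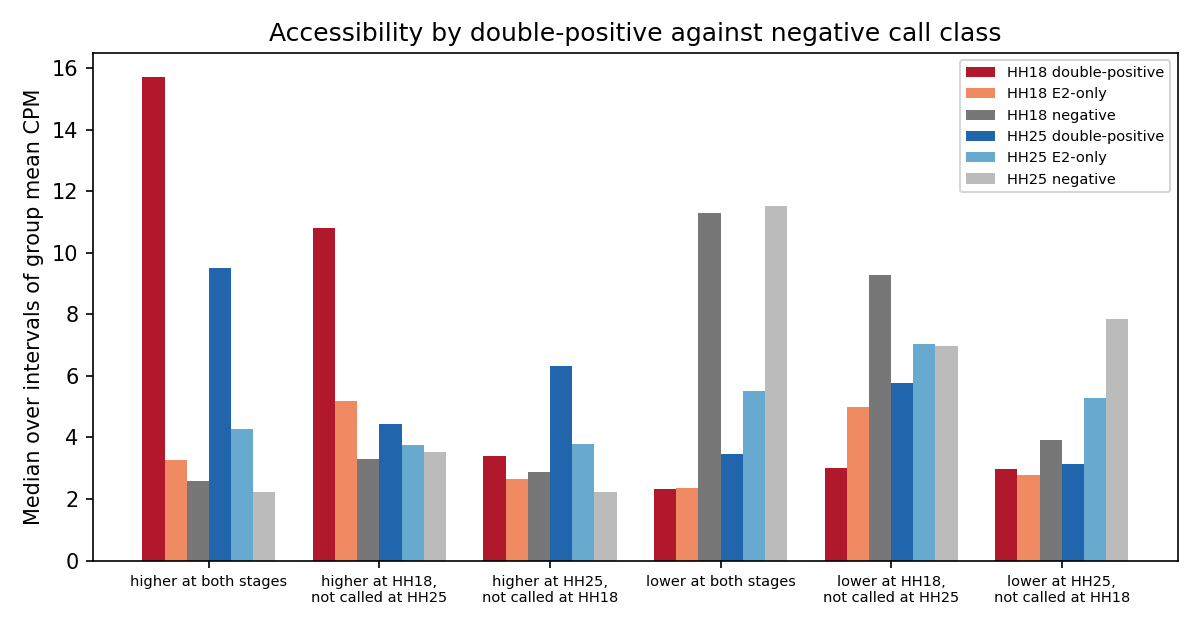
Median over intervals of the group mean CPM (y axis) for 6 classes of interval defined by the double-positive against negative calls at the 2 stages, 1 bar per group. Intervals were sorted into classes by these same values; those higher at both stages had medians of 15.7 CPM in HH18 and 9.51 CPM in HH25 double-positive cells.

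**Figure D5:**
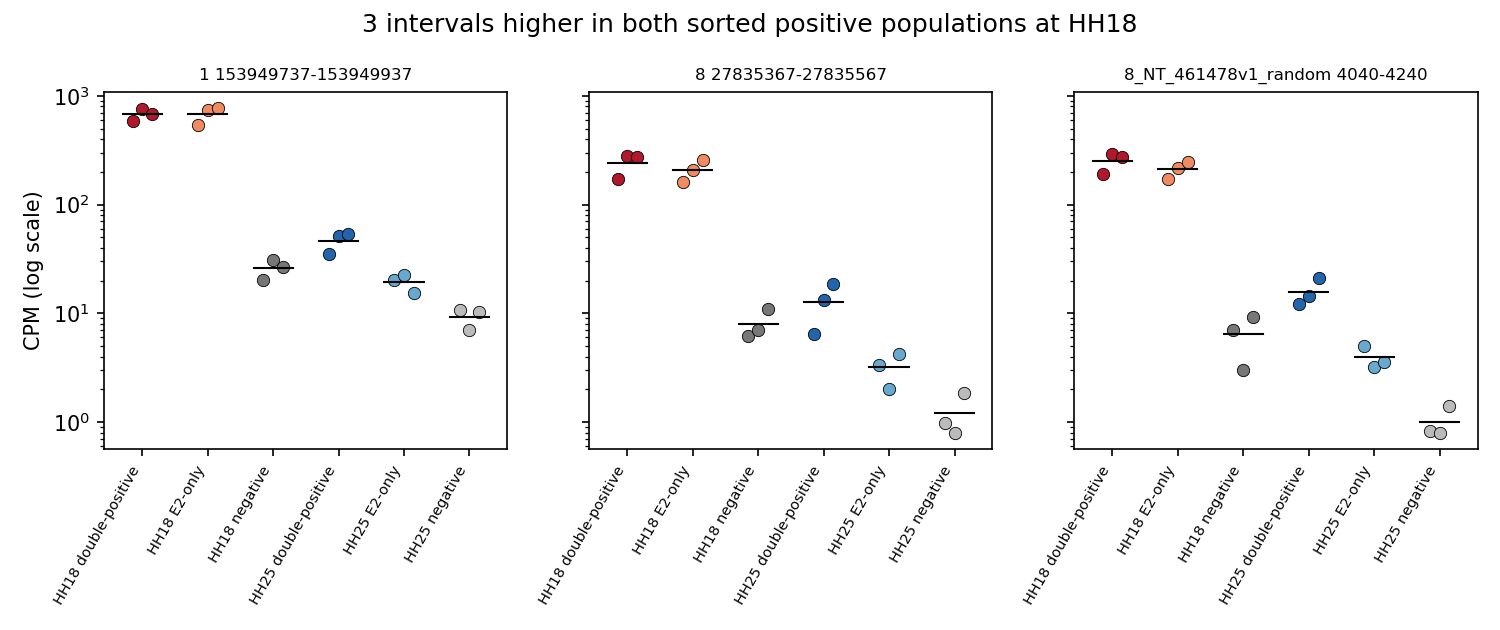
CPM on a log axis in each of 3 libraries per group (points) and their mean (line) for 3 intervals over 16-fold higher in both sorted positive populations than in negative cells at HH18. The interval on chromosome 1 had means of 674 and 679 CPM in those populations and 25.9 CPM in negative cells.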

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

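Every explanation test and every count of splits in this part was chosen after the results were seen, as was the E2-only interaction. The change from HH18 to HH25 differed between double-positive and negative cells at 9544 intervals and between E2-only and negative cells at 24375, each by the interaction test itself.

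Samples were also regrouped within each stage, with 100 splits drawn per interaction, the real one included. For double-positive cells 9 of the 100 splits gave at least 9544 calls, the highest other giving 29783. In 7 of the 8 other splits as large, most labels were exchanged at 1 stage only, as they were in 42 of the 91 smaller ones; exchanging labels at 1 stage turns the difference of the stages' contrasts into their sum. For E2-only cells 3 of 100 splits gave at least 24375 calls, the highest other giving 31190, and both others were of that kind. These splits therefore hold no case without an interaction to compare with, and whether chance gives either count was left open by them.

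For the pairwise comparisons 3 libraries against 3 make 10 splits, too few for a share under 0.05, and 1 split, the real one, gave the most calls in each. Every other split mixes libraries of the compared groups under 1 label, which raises the spread within groups. Few calls in those splits were therefore nearly assured, and they do not show what caused the real counts. Double-positive against negative cells gave 42871 calls at HH18 (highest other split 0) and 32535 at HH25 (1). E2-only against negative cells gave 46467 (5) and 14054 (3). Double-positive against E2-only cells gave 47806 (8) and 15623 (2). The stage comparisons gave 46553 in double-positive (1), 76118 in E2-only (0) and 32104 in negative cells (20).

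More intervals changed between stages in E2-only cells, 76118, than in double-positive (46553) or negative cells (32104). A difference in depth is argued against as the whole cause, since at equal totals the counts were 26252, 19560 and 9350, although the ratio of E2-only to double-positive calls fell from 1.64 to 1.34. One library is argued against as well: with any E2-only library left out the count was at least 68163. A difference between the HH18 and HH25 E2-only populations may remain, and was not tested apart from stage.

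Unplaced contigs are here all sequences other than chromosomes 1 to 33, Z and W; some carry a chromosome in their name without a position on it. Intervals on them were called higher in the double-positive interaction in 21.3% of cases, against 2.6% on assembled chromosomes. In the E2-only interaction it was 18.4%, against 8%. From HH18 to HH25 the share of reads on unplaced contigs went from 3.6% ± 0.32 (SD, n = 3) to 7.09% ± 0.11 in double-positive cells. From HH18 to HH25 their share of reads went from 3.6% ± 0.32 (SD, n = 3) to 7.09% ± 0.11 in double-positive cells. It went from 3.9% ± 0.24 to 5.99% ± 0.46 in E2-only and from 5.5% ± 1.04 to 5.75% ± 0.48 in negative cells. The share on chromosomes 11 to 33 also rose in double-positive cells, from 17.27% ± 0.05 to 20.63% ± 0.45 (negative cells 21.53% ± 0.71 to 22.65% ± 1.32). On chromosomes 1 to 5 it fell from 56.97% ± 0.17 to 52.01% ± 0.17. The double-positive interaction was called higher at 3.9% of intervals on chromosomes 11 to 33 and 2.1% on 1 to 5, the E2-only interaction at 8% on both. For double-positive cells scaling that varies with abundance and depth are argued against as the whole cause, since the share called was 20.4% with loess offsets (2.7% on chromosomes) and 18.1% at equal totals (1.7%). For E2-only cells it was 17.8% (8.1%) and 9.9% (4.9%), and depth as the whole cause is argued against by the log2 shift of contigs against chromosomes over libraries, 0.5 before and 0.42 at equal totals (95% interval 0.09 to 0.76). The 1652 double-positive calls lay on 1201 contigs, and the 10 contigs with most held 3.1% of them and 3.4% of the 1428 E2-only calls. The calls were thus spread widely. Contigs held few intervals each, so 10 could hardly have held most calls, and a class of related contigs is not excluded. Repeat content, GC content and mapping were not tested and may contribute, and a change in both sorted positive populations stays open.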

How the results depend on the processing

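Thinning all libraries to the lowest total left 55266 tested intervals and moved each count of calls by over 1.5 times: 22291, 18541 and 19392 at HH18 (double-positive against negative, E2-only against negative, double-positive against E2-only), 11839, 2597 and 4592 at HH25 in that order, 19560, 26252 and 9350 across stages for double-positive, E2-only and negative cells, and 2116 and 4780 for the double-positive and E2-only interactions. Depth and tested set changed together and were not separated. DESeq2 gave 7921 for HH25 E2-only against negative and 9851 for HH25 double-positive against E2-only; the cause was not tested. At an adjusted p below 0.01 the intervals lower at both stages in double-positive cells numbered 3021, those of E2-only cells 691 higher and 2128 lower, and those lower in double-positive than E2-only cells 243 (1317 with loess offsets; the cause was not tested). Of 145 such counts 127 stayed within 1.5 times.

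Leaving out 1 library gave 34211 to 40324, 35149 to 44459 and 41449 to 45866 calls for the HH18 comparisons in the same order, 24914 to 30906, 8990 to 12995 and 10644 to 12886 at HH25, 37414 to 40950, 68163 to 73936 and 19742 to 29674 across stages, and 5745 to 9431 and 17332 to 22929 for the interactions. The intervals higher at both stages numbered 11939 to 13053 for double-positive, 1134 to 1748 for E2-only and 5808 to 7741 for double-positive against E2-only, and those lower 3508 to 5532, 2232 to 3144 and 477 to 834. The 3508 and 477 were found without HH25 double-positive replicate 3.

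Deviations of same-numbered libraries correlated at -0.03 to 0.1, so the numbers were not taken as pairs. In HH25 E2-only and negative cells they correlated at 0.103, 0.064 and 0.023, each library most with its own number, a hint from the data and not the design. With the replicate block the counts were 42723, 47008 and 47729 at HH18 and 32791, 14357 and 15640 at HH25. Named intervals kept their direction in all 1767 values and lost the call in 19, of which 11 were chromosome 1 from 159624678 to 159624878 in the interaction. They were picked for the largest changes in the same data, so a kept direction was nearly assured. Entries that the filter of an alternative removed were not counted. Setting values of 1 to 0, halving counts and leaving out unplaced contigs were chosen after seeing the data, as were the E2-only interaction and the overlaps other than the double-positive one. The HH10 results, gene lists, motifs and GC correction were not run.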

Other observations

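The tests in this part were chosen after the data were seen. Called intervals lay beside each other more often than in shuffles within chromosomes. The shuffles did not keep abundance, on which calling depends, and no minimum distance was set. Clustering among intervals of like abundance or among separate elements was therefore not tested. Among neighbouring tested intervals within 20 kb, 27% of those higher in HH18 E2-only than negative cells were followed by another such interval, against 20.8% in 1000 shuffles within chromosomes (highest 21.5%; permutation p = 0.001, one-sided, the smallest these shuffles can give). For HH18 double-positive against negative cells the values were 24.3% and 19.8%.

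In windows of 100 kb with at least 8 tested intervals, the lowest adjusted p was on chromosome 15 from 9300000 to 9400000 (hypergeometric test over 8418 windows, adjusted p = 1.3e-06). There 19 of 24 intervals were more accessible in HH18 E2-only than double-positive cells and 1 was less. On chromosomes 11 to 33 as a class 20.6% of intervals were called in that direction and 13.1% in the other. The test took the share over all assembled chromosomes, 18.3%, and so did not allow for chromosome class. On chromosome 1 from 139800000 to 139900000, 16 of 22 intervals were higher in HH18 E2-only than negative cells (adjusted p = 0.0011). At HH25 the window on chromosome 9 from 900000 to 1000000 held 11 of 18 intervals higher in double-positive than negative cells (adjusted p = 0.018) and 10 of 18 higher than in E2-only cells (adjusted p = 0.003). Few windows had an adjusted p below 0.05: 8 of 8418 for intervals higher in HH18 E2-only than double-positive cells. There were 0 for those higher and 23 for those lower in HH18 double-positive than negative cells. Neighbouring intervals are not independent, so these values describe the windows.

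At HH18, 3 intervals were over 16-fold higher in both sorted positive populations than in negative cells: chromosome 1 from 153949737 to 153949937, chromosome 8 from 27835367 to 27835567, and 8_NT_461478v1_random from 4040 to 4240. Electroporated reporter DNA read by the assay is a candidate explanation: each fell in double-positive cells from HH18 to HH25, the smallest change being -3.85 on the log2 scale, below the 5th percentile of -2.82 among intervals higher in both populations. The 3 were picked by those same HH18 values, so a large fall was in part built in. Among 13 other intervals over 100 CPM in both populations the largest fall was -3.25, also below -2.82. The lowest change among all intervals higher in both populations was -6.14. An element of the genome that closed would fall too, so the 2 explanations cannot be told apart without the reporter sequences, not used here. The planned test at the reporters' own loci was not made, since genes were not located. The chromosome 8 interval and the contig kept 1 count ratio over 14 libraries (1.04; chi-square per degree of freedom 0.98), which is consistent with reads shared between near-identical copies.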
